A study of Mus musculus with 2 samples.

How the data were processed

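Total RNA from sorted mouse bone marrow cells was measured on 2 Affymetrix arrays, 1 from wild type mice and 1 from mice with conditional inactivation of TIF1γ (Trim33), here called TIF1γ Δ/Δ. Both samples were KLS cells, a stem and progenitor fraction that lacks lineage markers and carries c-kit and Sca. Per the labels' protocols, RNA was isolated with an RNeasy micro kit, and biotin-labelled cRNA was made with a two-cycle Affymetrix assay. The group of each array was taken from its genotype label. Each group held 1 array, so there were no replicates and no replicate check of any difference. No p-value, SD or standard error between samples could be given.

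The deposited values were probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version and any filter are not given in the sources used here, and detection calls were not used here. After trimming the lowest and highest 2% of the 45101 probe sets, the mean was 100 on each array, so the deposited intensities had already been scaled array by array. MAS5 subtracts mismatch signals, and low values from it are noisy, so a floor was set. The array number limits the precision of every value.

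The 64 control probe sets were left out. Of the others, 34945 were annotated to a single gene, 932 to several genes and 9160 to none in the platform annotation used. Symbols were updated by Entrez identifier to the mouse RefSeq annotation of GRCm38.p6, which held 34741 of the single-gene probe sets. No gene was named from a probe set with several genes. This left 18193 genes. A gene was represented by the probe set with the highest mean log2 signal.

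The difference was the log2 intensity of the TIF1γ Δ/Δ array minus that of the wild type array, less the median difference of probe sets measured on both arrays, which was -0.024. A probe set counted as measured when it reached the array's median signal over non-control probe sets, which was 14.4 on the wild type and 11.7 on the TIF1γ Δ/Δ array. For a gene under this floor on 1 array, the signal there was replaced by the floor, and the result is printed as at least N-fold. Because the floor was lower on the TIF1γ Δ/Δ array, bounds reached further in the direction of lower genes. A gene measured only on the TIF1γ Δ/Δ array could even get a value below 0, which is no bound in that direction. Hoxb6 (4.62 to 13.5, log2 -0.077), named after its value was seen, is an example. Such values entered the medians of the gene lists and of the random lists. Genes under the floor on both arrays have no fold. Genes at least 2-fold apart were counted by this rule of size alone.

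For each gene list with at least 5 measured genes, the median difference was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. A list stood apart when its median lay outside the central 95% of these. The percentile describes these 2 arrays and is not a test between genotypes. The 35 lists, the comparison, the main settings and the rule for named genes were fixed before the data were examined. Of the 786 list genes, 79 had no probe set of their own.

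By that rule the text names the TIF1 family, and the 8 genes with the largest positive and the 8 with the largest negative difference. These were taken among genes measured on both arrays whose measured probe sets all differed in the same direction. It also names the 4 brightest bounds each way and up to 4 members of each list at least 2-fold apart. Where a list had no such member, up to 2 of its brightest are given as values. Symbols of unnamed or predicted genes and immunoglobulin and T cell receptor segments were skipped in the choice of largest differences and bounds. Genes named outside the rule are marked as chosen after their values were seen.

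The scatter between probe sets of a gene was an SD of 0.452 on the log2 scale over 4534 genes. It measures disagreement of probe sets, not of mice. The procedure was tested on simulated data, in which the wild type array was set against a copy of itself, over 18193 genes. This scatter was added to the copy only, which can favour higher genes when the brightest probe set is chosen. All 50 genes made 4-fold higher and 49 of 50 made 4-fold lower were recovered. At 2-fold, 26 of 50 higher and 15 of 50 lower genes were recovered. Of 40 unchanged lists, 1 was called apart. These were random draws of genes with independent scatter, so they do not test lists whose genes vary together.

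The alternatives covered scaling (none, quantile, loess), the floor (40th percentile, 65th percentile, none), the probe set rule (mean of all, or without probe sets shared between transcripts), a pseudocount, thresholds of 1.5-fold and 3-fold, agreement of probe sets, the list mean, and random lists without matching. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.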

Results

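Gene expression was compared between KLS cells of wild type mice and of mice with conditional inactivation of TIF1γ, a member of the TIF1 family of transcriptional regulators, to describe the effect of the deletion on haematopoietic stem cells. The data were 1 array per genotype, so every difference below compares 2 arrays and has no replicate check. Of 18193 genes, 11074 were measured on the wild type array and 11015 on the TIF1γ Δ/Δ array, and 10365 on both. The log2 signals of these 10365 genes correlated with r = 0.953 across genes, which are not independent replicates. The ratio of 3' to 5' signal of Gapdh was 7.86 on the wild type and 7.38 on the TIF1γ Δ/Δ array, and that of actin was 5.14 and 5.54.

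The targeted gene, Trim33, was lower on the TIF1γ Δ/Δ array. Its brightest probe set, 1426954_at, gave 379 on the wild type and 172 on the TIF1γ Δ/Δ array, a log2 difference of -1.12 or 2.17-fold. The probe set 1455189_at gave 61.0 and 34.5 (log2 -0.80), and 1459264_at lay under the floor on both arrays. Whether any of these lies in the deleted part of the gene is not given in the sources used here, so the lower signal is only a limited check of the labels. Of the other TIF1 family members, Trim24 gave 74.8 and 77.9 (log2 0.082) and Trim28 gave 2016 and 2631 (log2 0.41), while Trim66 lay under the floor on both arrays.

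The genes furthest apart were lower on the TIF1γ Δ/Δ array, and many are known from mature myeloid cells. Camp, an antimicrobial peptide of neutrophil granules, gave 3951 on the wild type and 12.7 on the TIF1γ Δ/Δ array (log2 -8.26). Ngp gave 5665 and 29.7 (log2 -7.55) and S100a8 gave 9568 and 53.6 (log2 -7.46). Lgals3 (log2 -6.37), Wfdc21 (log2 -5.49), the macrophage mannose receptor Mrc1 (log2 -4.32), the iron exporter Slc40a1 (log2 -4.18) and Fabp4 (log2 -4.13) followed. Among genes under the floor on the TIF1γ Δ/Δ array, S100a9 was at least 688-fold, Chil3 at least 268-fold, Lcn2 at least 188-fold and Vcam1 at least 115-fold lower.

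Rank by rank, the differences in the other direction were smaller. The 8 genes with the largest positive difference were Lrmda (16.0 to 369, log2 4.55), Wdr48 (log2 3.22), the inhibitory Fc receptor Fcgr2b (226 to 1699, log2 2.93), Mtmr9 (log2 2.71), the heat shock gene Hspa1b (log2 2.54), the platelet chemokine Ppbp (log2 2.42), Hyou1 (log2 2.35) and Fam102b (log2 2.10). All 4 measured probe sets of Fcgr2b and all 3 of Mtmr9 were higher, whereas 1 of the 3 measured probe sets of Wdr48 differed by a log2 of only 0.14. Of genes under the floor on the wild type array, Nacc1 was at least 3.91-fold, Camk2b at least 3.12-fold, Steap3 at least 2.96-fold and Irf2bpl at least 2.77-fold higher.

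In all, 297 genes were at least 2-fold higher and 705 at least 2-fold lower on the TIF1γ Δ/Δ array, and lower genes made up 70.4% of these. At least 8-fold, 2 genes were higher and 53 lower. Bounds accounted for 25 of the higher and 223 of the lower genes; among genes measured on both arrays, 272 were higher and 482 lower. In the simulation with no change, probe set scatter alone placed 214 genes at least 2-fold higher and 150 lower. The count of higher genes lay little above this. The simulation is only a rough guide, since scatter was added to the copy only, which can favour higher genes. That scatter also measures disagreement of probe sets, not of arrays or mice. For 64 of the counted genes the probe sets disagreed in direction.

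**Figure D1:**
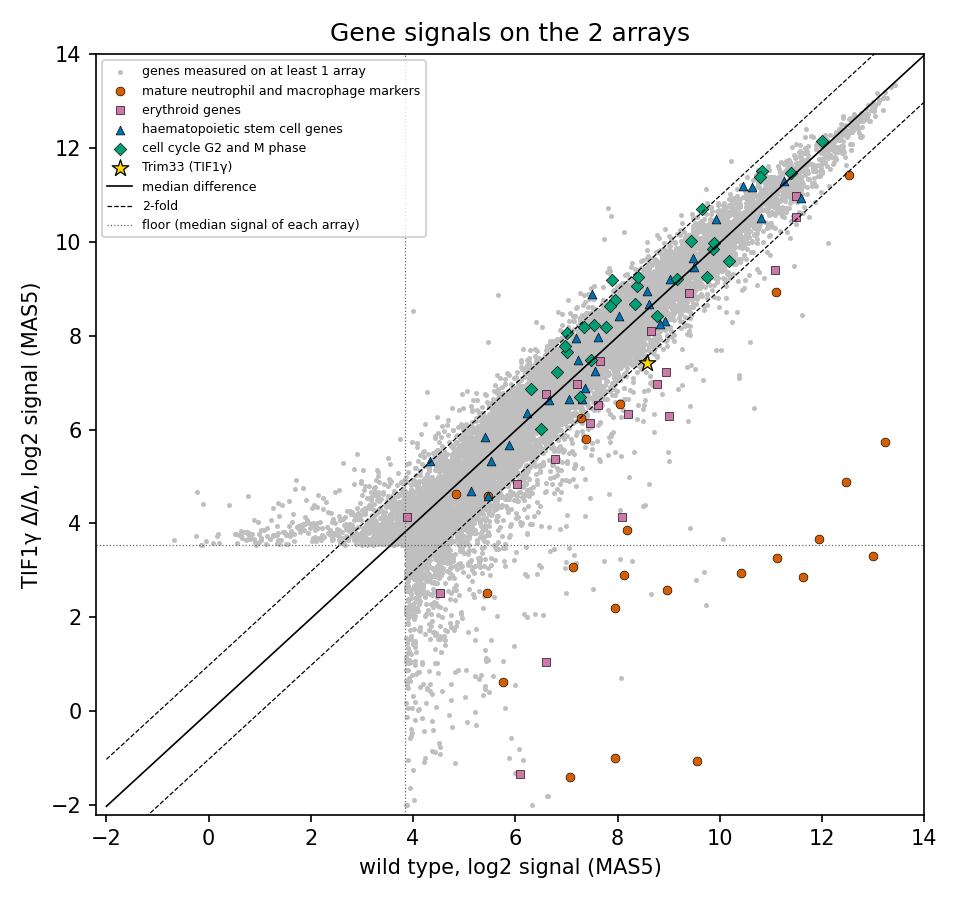
Log2 signal of each gene measured on at least 1 array, wild type on the horizontal and TIF1γ Δ/Δ on the vertical axis, with genes of 4 lists coloured and Trim33 as a star. The solid line is the median difference, dashed lines are 2-fold, dotted lines are the floors, and signals under 0.25 are drawn at 0.25; S100a9 (8147 and 9.92) and other neutrophil and macrophage markers lie far below the dashed lines.

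Of the 33 lists large enough for a percentile, 16 stood apart from random lists, 6 higher and 10 lower. For lists of unrelated genes, 1.65 would be expected outside by chance. Genes within a list can vary together between any 2 samples, so more could fall outside without an effect of genotype. The lists also share genes and are not independent of each other.

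Markers of mature neutrophils and macrophages were lower almost throughout. Of 24 measured members, 22 were at least 2-fold lower and none higher, with a median of -4.35, below that of all 10000 random lists. On the TIF1γ Δ/Δ array 11 of the 24 reached the floor, against 24 on the wild type array. Genes of granulocyte-monocyte progenitors were lower with them, at a median of -0.84 that no random list reached. Of 25 measured, 9 were at least 2-fold lower and 2 higher. Csf1r, the receptor for macrophage colony-stimulating factor, gave 684 and 91.1 (log2 -2.88, 3 of 3 probe sets), Ly86 had a log2 difference of -3.43, and Igsf6 was at least 9.17-fold lower. The 2 higher members were Fcgr2b (log2 2.93) and Cebpa (log2 1.39).

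Erythroid genes were also lower, with 12 of 21 measured members at least 2-fold lower, none higher, and a median of -1.16 below all random lists. The band 3 anion exchanger Slc4a1 had a log2 difference of -3.91 and Blvrb of -2.70, while Trim10 was at least 8.24-fold and the haem synthesis enzyme Alas2 at least 5.79-fold lower. The neutrophil and macrophage markers (median -4.35) were lower on the same array. Megakaryocyte and platelet genes did not stand apart. Their median was 0.15 at percentile 74.2, and 3 of 23, namely Ppbp (log2 2.42), Tubb1 (log2 1.54) and Itgb3 (log2 1.34), were at least 2-fold higher. Mast cell and basophil markers had a median of 0.32 at percentile 89.6, with 1 of 10, Gata2, at least 2-fold higher.

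Lymphoid and antigen presentation lists had lower medians on the TIF1γ Δ/Δ array, as did the neutrophil and macrophage markers. For MHC class II and dendritic cell markers the median was -0.90, below all random lists, with 5 of 14 at least 2-fold lower. H2-Eb1 (log2 -3.25), Cd74 (log2 -2.36), H2-Ab1 (4.58-fold, 3 of 3 probe sets) and H2-Aa (log2 -2.11, 4 of 4) were among them. The list planned for mature B cell and plasma cell markers had a median of -0.66 (percentile 0.110). On the TIF1γ Δ/Δ array 8 of its 12 measured members reached the floor, and 4 of the 12 were at least 2-fold lower. These included Ms4a1 (at least 10.7-fold) and Vpreb1 (log2 -2.62), which is a gene of B cell precursors. Jchain, named after its value was seen, gave 4346 and 4440 (log2 0.055). T cell and NK cell markers had a median of -0.53 (percentile 0.905), and 5 of 15 were at least 2-fold lower. These included Gzma (at least 4.26-fold), Klrd1 (log2 -1.93) and Ccl5 (log2 -1.31). On the TIF1γ Δ/Δ array 8 of the 15 reached the floor, so the values of the others are bounds. Cd8b1 (15.3) and Cd3g (16.8), named after their values were seen, lay near the floor of 14.4 on the wild type array too. Lymphoid priming genes had a median of -0.39 (percentile 0.105), with 7 of 23 lower and 2 higher. The 2 higher, named after their values were seen, were Satb1 (log2 1.16, 3 of 4 probe sets) and Mef2c (log2 1.03, 5 of 5). Dntt, also named afterwards, was at -0.017. Cd52 (log2 -1.28) and Blnk (at least 3.88-fold) were lower, whereas Igll1 (log2 -2.42) was at 0.96 without probe sets shared between transcripts.

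Haematopoietic stem cell genes did not stand apart. Their median was 0.079 at percentile 57.4, and 28 of 30 measured members were under 2-fold apart. Gata2, a stem cell transcription factor, gave 182 and 472 (log2 1.40), and the receptor Tek had a log2 difference of 1.02. Genes higher in aged stem cells had a median of -0.18 (percentile 8.76), with Plscr2 (log2 -1.47) lower and Itgb3 higher among 19. Of 31 haematopoietic transcription factors, 4 were higher and 1 lower at 2-fold, at a median of 0.20 (percentile 86.4); Cebpa (log2 1.39) and Runx3 (log2 1.14) were higher and the erythroid factor Klf1 (log2 -1.71) lower. None of 12 Hox genes was 2-fold apart (median -0.17, percentile 49.3), with Hoxa9 at log2 0.55 and Hoxa5 at -0.17.

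Cytokine receptors had a median of -0.051 (percentile 23.4) but a mean of -0.28, and 4 of 24 were at least 2-fold lower, namely Csf1r, Il18r1 (log2 -1.31), the erythropoietin receptor Epor (log2 -1.16) and Csf2ra (log2 -1.13, 1 of 2 probe sets). Adhesion and homing genes had a median of -0.012 (percentile 32.1), with the chemokine receptor Cxcr4 (log2 -2.60) and Itgb2 (log2 -1.62) lower among 21. Chromatin regulators mutated in myeloid disease had a median of 0.12 (percentile 60.8), and among 24 Tet2 was lower (log2 -1.53, 2 of 2 probe sets) and Dnmt3b higher (log2 1.02).

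Genes of the G2 and M phases were higher on the TIF1γ Δ/Δ array. Of 29 measured, 24 had a positive difference but only 3 reached 2-fold, and the median of 0.58 was above that of all random lists. The mitotic checkpoint kinase Bub1b (log2 1.32, 3 of 3 probe sets), Tpx2 (log2 1.06, 3 of 3) and Top2a (log2 1.07, 1 of 2) reached it. The 5 members below 0, named after their values were seen, were Cdk1 (log2 -0.56), Cenpf (log2 -0.55), Mki67 (log2 -0.48), Cenpe (log2 -0.47) and Birc5 (log2 -0.33). The neutrophil and macrophage markers (median -4.35) differed in the opposite direction. Genes of the G1 and S phases had a median of 0.22 at percentile 97.1, inside the central 95% although it stood apart under 5 of 11 alternative settings, with Uhrf1 (log2 1.66) and Pola1 (log2 1.36) at least 2-fold higher among 29.

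Among 15 cyclin D, CDK4, CDK6 and CDK inhibitor genes, Ccnd1 (log2 1.56, 3 of 3 probe sets) and Cdkn1a (2.83-fold, 2 of 2) were at least 2-fold higher, at a list median of 0.23 (percentile 78.3). The p53-responsive genes had a median of 0.0052 (percentile 61.9), with Cdkn1a and Plk2 (log2 1.12) higher among 21. Apoptosis regulators had a median of -0.0057 (percentile 41.5) but a mean of 0.035, and Bcl2 (log2 1.36) and Casp9 (log2 1.20) were higher and Bmf (log2 -1.66) lower among 21.

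TIF1γ is known as a regulator of TGF-beta signalling. Components of the TGF-beta and BMP pathways had a median of 0.32 (percentile 98.7), and 1 of 25, the receptor Acvr1b (log2 1.02), reached 2-fold. The list stood apart under 6 of 11 alternative settings, which did not include quantile or loess scaling, and the neutrophil and macrophage markers differed in the opposite direction. TGF-beta-responsive genes had a median of -0.14 at percentile 30.7, inside the random lists, but a mean of -0.38, with 6 of 19 at least 2-fold lower and 1 higher. The median was -0.42 with the mean of all probe sets, which takes in those under the floor, the only 1 of 11 alternative settings under which this list stood apart. Id2 (1046 to 207, log2 -2.31), Tgfbi (log2 -2.03) and Fn1 (at least 3.62-fold) were lower, beside the lower neutrophil and macrophage markers, and Cdkn1a was higher.

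Interferon-responsive genes were lower, with a median of -0.45 (percentile 0.010), 23 of 26 below 0 and 4 at least 2-fold lower. These were the double-stranded RNA sensor Eif2ak2 (log2 -1.79), Iigp1 (log2 -1.27), Ifit3 (log2 -1.11) and Rsad2 (log2 -1.03). NF-kappaB and inflammatory genes had a median of -0.47 (percentile 0.285), with Cd83 (at least 6.21-fold), Cxcl2 (log2 -1.89) and Ptgs2 (log2 -1.12) lower among 19. That list stood apart under 9 of 11 alternative settings. Both lists were lower together with the neutrophil and macrophage markers. Immediate early and stress genes had a median of 0.0012 (percentile 44.3), a mean of -0.0043, and went both ways, from Hspa1b (log2 2.54) and Klf6 (log2 1.10) to Klf4 (log2 -1.67) and Ddit3 (log2 -1.09).

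The list planned for haem, cholesterol and lipid synthesis held no haem enzyme, so its 17 measured genes describe sterol and fatty acid synthesis only. The median was 0.41 (percentile 98.4), with Scd2 (log2 1.42), the sterol enzyme Sqle (log2 1.37) and the fatty acid synthase Fasn (log2 1.12) higher and Scd1 (log2 -1.62) lower. Glycolysis genes had a median of 0.33 (percentile 97.8), with Hk2 (log2 1.28) higher and Ldhb (log2 -1.20) lower among 18, and stood apart under 8 of 11 alternative settings. Oxidative phosphorylation genes had a median of -0.16 (percentile 1.74), and none of 32 was 2-fold apart; Atp5c1 was at log2 -0.10 and Cox5a at -0.17. This list, too, stood apart under 8 of 11. Cytosolic ribosomal proteins had a median of -0.14 (percentile 12.2), none of 23 was 2-fold apart, and Rps18 was at -0.024 and Rpl35 at -0.36. Transcription elongation factors had a median of 0.37 (percentile 97.6), with Mllt1 (log2 1.46) and Ctr9 (log2 1.17, 2 of 4 probe sets) higher among 21. With the mean of all probe sets this list was no longer apart. The neutrophil and macrophage markers (median -4.35) and erythroid genes (median -1.16) were lower on the same array, in the opposite direction to the lipid, glycolysis and elongation lists and in the same direction as oxidative phosphorylation.

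Bone marrow stroma and endothelium markers had a median of 0.44 (percentile 99.3) but a mean of -0.038, over 11 genes of which 2 were higher and 2 lower. Pdgfrb (log2 1.27) and Emcn (at least 2.03-fold) were higher, and Lpl (log2 -2.40) and Cxcl12 (log2 -1.16) lower. The list stood apart in that direction under 6 of 11 alternative settings. The median was -0.13 with the floor at the 40th percentile and -0.81 at the 65th, and the neutrophil and macrophage markers were lower on the same array. Genes next to Trim33 on its chromosome had a median of 0.17 (percentile 81.8) and stood apart under 1 of 11 alternative settings, with Tspan2 (log2 1.08) higher and Ap4b1 (log2 -1.10, 1 of 2 probe sets) lower among 16. The 4 measured sex-linked genes were all under 2-fold apart, with the Y-linked Eif2s3y at log2 -0.77 and Kdm5d at 0.14.

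**Figure D2:**
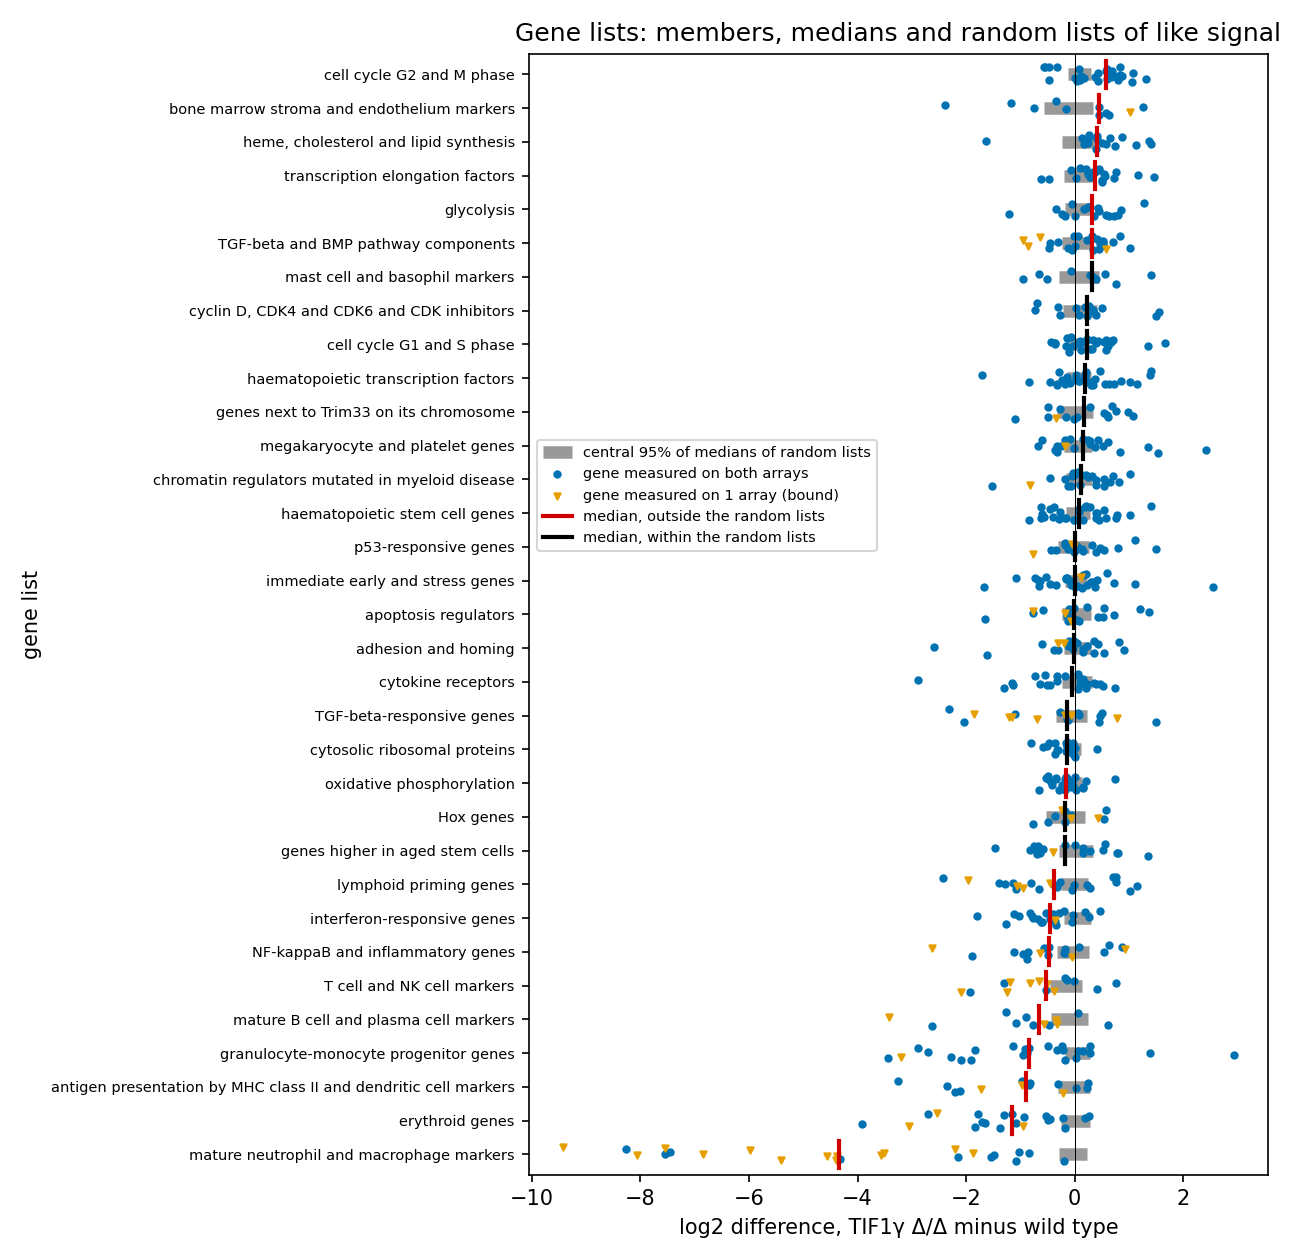
Log2 difference, TIF1γ Δ/Δ minus wild type, of the members of the 33 gene lists (points, with triangles for bounds) and the median of each list (bar, red when outside the random lists). Grey bands are the central 95% of medians of 10000 random lists; the neutrophil and macrophage list (median -4.35) lies furthest below its band and the G2 and M list (median 0.58) above its own.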

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

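The tests of further neutrophil and erythroid genes and of chromosome neighbours were written before their results were seen, and the other tests in this part were chosen afterwards.

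Signal in probe sets without an annotated gene was not part of any comparison. Of 9160 such probe sets, 2174 were measured on both arrays, and 41 of these were at least 2-fold higher and 328 at least 2-fold lower on the TIF1γ Δ/Δ array. The largest positive differences were those of 1455869_at, from 62.0 to 842 (log2 3.79), and 1442118_at, from 20.1 to 116 (log2 2.55).

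Genes of mature neutrophils, macrophages and erythroid cells were far lower on the TIF1γ Δ/Δ array, although the sort selects against lineage-positive cells. Neutrophils and erythroid cells in the wild type sample are a candidate source, with S100a8 at 9568 and Ngp at 5665 on that array. Further neutrophil genes had a median of -0.98 and further erythroid genes of -0.71, both below all random lists, after 9 and 15 genes that were in the fixed lists or already looked at had been removed. A lower share of the sorted cells, with every other cell type raised alike, was taken to need like medians. The 8 lists of other cell types spread over 4.79 (log2). This spread cannot decide it, because medians also depend on the floor and on the sorted cells' own signal for the markers. The highest median, 0.44 for stroma and endothelium, turned to -0.81 with the floor at the 65th percentile. Scaling left the neutrophil and macrophage median at -4.18 or lower. That the deletion lowers these genes within KLS cells predicts the same direction and cannot be told apart with 1 array per genotype.

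Genes of the G2 and M phases were higher. Dilution of the wild type RNA by other cells would raise stem cell genes alike. The stem cell list's median was 0.079, inside its random lists, and the G2 and M median exceeded it by 0.51. The SD of random medians was 0.11 for each of these lists. The rule for this test was the SD of the stem cell members' differences, which went both ways. That SD was 0.54, and the gap of 0.51 lay within it. Dilution was therefore not excluded, alone or as a part of the difference. A signal-dependent trend would vanish under loess scaling, where the median was 0.49 and still outside the random lists. An effect of the deletion in the sorted cells may account for it, and cannot be told apart from a difference between the 2 samples with 1 array per genotype.

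Among the 8 genes with the largest positive difference, which are the same 8 without the rule on agreeing probe sets, a fault of a single probe set would leave a gene's other probe sets unmoved. For Fcgr2b, Mtmr9, Fam102b and, by a bound, Lrmda, the lowest log2 difference of another informative probe set was 1.83, against that explanation. Informative meant measured on both arrays or with a bound of at least 2-fold, a rule that favours high bounds. It left out 1431988_at of Lrmda (10.3 to 19.8), so Lrmda rests on 1 bound. A fault of a single probe set cannot be told apart for Wdr48, whose other measured probe sets were at 1.41 and 0.14. Nor can it for Hspa1b, whose 1427127_x_at gave only a bound of at least 2.23-fold. The same holds for Ppbp and Hyou1, which had no other informative probe set. A chromosome segment of another strain could raise neighbours too. Of 80 neighbouring genes 11.3% were at least 2-fold apart, against 8.55% of all genes, and 25.2% of 10000 random draws had as high a share, which does not exclude a variant acting on 1 gene.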

How the results depend on the processing

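The counts without genes of other cell type lists and with only genes measured on both arrays were chosen after seeing the data; the other alternatives were fixed before. Between quantities without replicates, the SD between probe sets served as the yardstick for single genes and the SD of random medians for lists. The counts of 297 higher and 705 lower genes became 170 and 412 with the floor at the 65th percentile, 2025 and 2784 with no floor, 1579 and 1791 at 1.5-fold and 26 and 266 at 3-fold. What moved them was not tested. Without the genes of the 8 lists of other cell types, 291 were higher and 655 lower. These lists hold only part of the genes of such cells, so the count cannot show how many lower genes come from them. Outside the fixed lists, 10 of 21 further neutrophil and 5 of 18 further erythroid genes were at least 2-fold lower. The share of lower genes, 70.4%, ranged from 53.1% at 1.5-fold to 91.1% at 3-fold, with 57.9% under no floor and 62.3% under quantile scaling. Trim33 stayed lower under all 9 settings. Its -1.77 with the mean of all probe sets takes in 1 under the floor on both arrays; the measured ones gave -1.12 and -0.80. The stroma and endothelium median turned to -0.13 (40th percentile floor), -0.81 (65th) and -0.24 (mean of probe sets). With the mean of all probe sets Top2a was at -0.50, Pola1 at -0.31, Ptgs2 at 0.042 and Mllt1 at -0.048. Each had 1 probe set under the floor on at least 1 array. Over probe sets measured on both arrays, the means kept the main direction. They were 0.49 for Top2a, 1.36 for Pola1, -1.12 for Ptgs2 and 1.46 for Mllt1. For the last 3 genes this was the main probe set alone. For Mllt1 the plain mean was 0.21, and -0.048 is the value with the floor applied to the mean. Without shared probe sets Igll1 was at 0.96. The cause of the changes of Igll1 and of the stroma and endothelium median was not tested. Of 991 values of 113 named genes, 896 stayed within that SD, 90 moved by more and 5 called values reversed; 26 had no value. Of 296 list medians, 249 stayed, 44 moved and 3 reversed. Between 13 and 16 lists stood apart. Of the 16 in the main setting, 10 stood apart in the same direction under all 11 settings: neutrophil and macrophage, erythroid, granulocyte-monocyte progenitor, lymphoid priming, B cell, T and NK cell, MHC class II, interferon, G2 and M, and lipid synthesis. No paired analysis was possible because each group held 1 array, and no replicate could be left out. Signals near the floor limit the folds of dim genes, where probe sets scattered more (SD 0.510 in the dimmest part against 0.356 in the brightest).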

Other observations

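The tests of endoplasmic reticulum chaperones and of ribosome biogenesis genes were written before their results were seen, and the macrophage tests were chosen after macrophage genes had been seen lower. The genes in this part were chosen after their values were seen.

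Globin signal was much lower on the TIF1γ Δ/Δ array. Probe sets shared by several alpha globin genes gave 5690 and 152 (log2 -5.20) and 5024 and 61.5 (log2 -6.33), and another probe set was at least 74.4-fold lower. A probe set shared by beta globin genes gave 5311 and 404 (log2 -3.69). These cannot be assigned to a single gene. Surface proteins and regulators that mark KLS and stem cells differed far less, with Kit at log2 0.39, Cd34 at 0.76, Procr at -0.60, Mecom at 0.42, Slamf1 at 0.16 and Hlf at -0.0054.

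Genes of ribosome biogenesis and Myc responses may be higher as a group, a hypothesis raised by Ccnd1 (log2 1.56) and the amino acid transporter Slc7a5 (log2 1.59). A list without these genes had a median of 0.41 at percentile 99.9, with 26 of 28 above 0 and 2, Cad (log2 1.21) and Polr1b (log2 1.01), at least 2-fold higher. The neutrophil and macrophage markers (median -4.35) and erythroid genes (median -1.16) differed in the opposite direction, so other cells in the wild type sample stay open as an explanation. Hyou1, an endoplasmic reticulum chaperone, was higher, but 20 other chaperone genes had a median of 0.20 at percentile 87.5 and none was 2-fold apart, with Hspa5 and Calr also members of fixed lists, so a wider rise of that group was not seen.

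Vcam1, C1qb and Slc40a1, all known from bone marrow macrophages, were far lower. The macrophage and monocyte members of the list fixed beforehand, without Vcam1 and C1qb, had a median of -1.87 below all random lists, and 8 of 10 were at least 2-fold lower. They belong to the list in which 22 of 24 were already known to be at least 2-fold lower. Their result follows from that and adds no support. A list of other macrophage genes, written after that pattern was seen and without 4 genes already looked at, had a median of -1.59, and 7 of 10 were at least 2-fold lower. The genes of this second list were thus lower as a group, which does not show whether the cells or their expression differed.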
